A study of Mus musculus with 6 samples.

How the data were processed

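Total RNA of 6 male mesonephroi at E12.5 was extracted with a PicoPure kit, selected for poly(A), and sequenced as paired reads of 150 bases, per the labels' protocols. Per the submitters' processing notes, the submitters used the mouse genome build GRCm39 and DESeq2. The aligner, the counting tool, its strand setting, the annotation release and any filter on genes are not given in the sources used here. The deposited table holds 1 row for each of 20033 genes, with an Ensembl identifier and a symbol, and no positions, so no coordinates are given. The authors deposited 1 TPM column per embryo (which corrects for gene length and library size), per the file headers, and each column has the same sum over the table. The authors' log2 fold change of knockout over control, its p-value and its adjusted p-value are deposited in the same table, per the file headers; the adjusted p is empty for 1175 genes. Over 12771 genes with a mean of at least 5 TPM, those log2 values had a Pearson r of 0.9998 with the log2 ratio of mean TPM of knockout over control, so they run in that direction, although values near 0 differ in sign for some genes, such as Gli1. The authors' values are quoted only where they are named as such.

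Samples were grouped by their titles, as 3 controls and 3 knockouts. The genotype field calls the controls heterozygous and the design text calls them wild type. The labels give no litter, batch or date. Mice are numbered 1 to 3 in both groups. The neighbours of Wnt9b were fixed by name. The reference annotation at hand was of another build than the authors' one and was used for no value.

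The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. That design planned a quasi-likelihood test on counts. The deposited values are TPM, so the test written for that case was used: limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend, genotype as the only term, and genes of at least 1 TPM in at least 3 libraries. Adjusted p-values are by Benjamini and Hochberg over 17577 genes, and 0.05 was the threshold. A difference on the log2(TPM + 1) scale understates the change of low genes. Standard errors are limma's moderated ones. The 34 gene lists with at least 5 tested genes were compared with all other genes by limma's camera, two-sided, with the preset correlation between genes of 0.01 and adjustment over the lists; sex-linked genes and neighbours of Wnt9b served as checks outside that family. In each list, genes were counted over all genes tested and again adjusted over the list alone. Shares of TPM were compared by exact permutation tests, for which 3 against 3 cannot go below p = 0.1.

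Genes were named as follows: Wnt9b first, then, among genes past the test with a mean of at least 1 TPM in the higher group and no overlap between the groups, the 12 largest increases and the 12 largest decreases. Predicted genes without a proper symbol, pseudogenes and genes of the Y chromosome or of X inactivation were passed over. From each list, up to 4 members past the test were named, by adjusted p, or where there were none at most 2 members of highest level. A fixed set of Wnt, androgen, duct and nephron genes was named whatever the outcome, apart from some not used here. Igfbp3, Igfbp2 and the genes given as values of single libraries fall outside that rule and were chosen after their values were seen.

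TPM keeps no depth, but the ratio of a gene's values between libraries is that of its reads times a factor per library. The 6 values of 20030 of 20033 genes came out as whole reads within 0.02 reads. As a check on 1000 genes and up to 4000 reads, 93.5% came out whole as deposited and 0.1% after random changes of the values. A factor common to all 6 libraries of a gene is lost and Rn18s-rs5, mt-Co1 and Eef1a1 were not recovered, so the totals are lower bounds. They were 32401829, 28408890 and 28154335 for controls 1 to 3 and 31184586, 27930310 and 28758347 for knockouts 1 to 3. Between libraries of a group, the chi-square of these reads per degree of freedom was at least 8.16, so none of the libraries repeats another, and the spread between embryos exceeds counting noise.

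The steps were tested on simulated reads for these 6 libraries (5 runs, 17770 genes). For the knockout against control comparison, 24.2% of genes changed 1.5-fold and 59.8% of genes changed 2-fold were called, 6.46% of calls were false, and no gene was called in runs without a change. Lists changed 1.3-fold were called in 100% of cases with the preset correlation and 96.0% with an estimated one. The genes were simulated independently and the lists drawn at random. These rates therefore do not show how either setting handles lists of genes that vary together. The alternatives were scaling by median ratios or upper quartile, no filter, a pseudocount of 0.1 without a filter, a change over 1.2-fold (limma treat), removal of erythroid genes, limma-voom on the recovered reads, a replicate block, and omission of each library. For lists they were camera with an estimated correlation or on ranks, and fry. Chosen after seeing the data were a filter at 5 TPM, a pseudocount of 0.1 with the filter kept, and library weights in limma. A DESeq2 test planned on counts was not run here, since the main unit is TPM; the authors' deposited adjusted p stands beside it.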

Results

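Gene expression was measured by RNA sequencing in mesonephroi of 6 male mouse embryos at E12.5, 3 labelled control and 3 labelled knockout for Wnt9b. The mesonephros is the transient kidney of the embryo. It holds the mesonephric tubules, the mesenchyme around them and the Wolffian duct, from which the epididymis and vas deferens form under androgens, and it lies against the gonad. Wnt9b is a secreted Wnt ligand of the duct epithelium, and the knockout was global. The data come from a study of the Wolffian duct and androgens and allow 1 comparison, knockout against control. One label calls the controls heterozygous and another calls them wild type, so they are called controls here. Lower bounds on the reads assigned to genes, recovered from the deposited values, ran from 27930310 to 32401829 per library. Each library came from its own embryo per the labels, and the litters and batches are not given.

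Wnt9b itself (ENSMUSG00000018486) was measured at 24.9, 26.4 and 34.0 TPM in the 3 control libraries and at 23.4, 19.2 and 19.0 TPM in the 3 knockout libraries. The knockout values lay below every control value, but the log2 difference of -0.44 (SE 0.14; limma adjusted p = 0.266) did not pass the test. The authors' deposited table gives a log2 fold change of -0.45 with an adjusted p of 0.0263 for this gene. A gene-level value counts reads from any part of the locus. Transcripts left after a deletion of some exons stay in it, so it gives little check of the genotype labels. The Y-linked genes Ddx3y and Eif2s3y were present in all 6 libraries, at no less than 60.1 and 56.7 TPM, and Xist did not exceed 0.206 TPM, as the male label requires. None of 4 tested sex-linked genes passed limma over all genes (0 at an unadjusted p under 0.05; 0 in the authors' deposited table). 0 were higher and 0 lower when adjusted over the list alone. None of 7 tested genes that neighbour Wnt9b passed limma over all genes (0 at an unadjusted p under 0.05; 0 in the authors' deposited table). The counts adjusted over the list alone were 0 higher and 0 lower. Gosr2 and Kansl1, those of highest level, had log2 differences of -0.0099 and -0.073. Myl4, a neighbour under the filter, has a log2 fold change of 1.97 and an adjusted p of 0.0380 in the authors' deposited table.

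In the knockout mesonephroi, Notum, a secreted enzyme that inactivates Wnt ligands, was at 43.5 ± 1.82 TPM (mean ± SD, n = 3) against 86.4 ± 0.467 TPM in controls. Lhx1, a transcription factor gene needed for the duct and tubules, was also lower, at 9.03 ± 1.46 against 24.0 ± 2.99 TPM. Genes of the gonadal soma were higher: Nr5a1, needed for gonad and adrenal formation, was at 21.6 ± 3.10 against 6.55 ± 2.54 TPM, and Gata4 at 38.0 ± 4.22 against 10.8 ± 5.43 TPM. The gene with the smallest p was Igfbp3 (ENSMUSG00000020427), which encodes a secreted binding protein of insulin-like growth factors. It fell from 1318 ± 18.7 to 552 ± 47.8 TPM, a log2 difference of -1.26 (SE 0.073; limma adjusted p = 0.00181), and Igfbp2 of the same family fell from 643 ± 17.4 to 410.2 ± 34.4 TPM. Among 17577 genes tested, 78 differed at an adjusted p under 0.05 (limma on log2(TPM + 1)), 23 higher and 55 lower in the knockouts. The 2 groups did not overlap for any of these genes, nor for 16.6% of all tested genes, where chance gives 10%. The authors' deposited table marks 670 genes at an adjusted p under 0.05, 260 higher and 410 lower, among them 77 of the 78, and limma-voom on the recovered reads called 295. The count changed with single libraries: it was 28, 13 and 14 without control 1, 2 and 3, and 33, 23 and 243 without knockout 1, 2 and 3. Of the 40 called genes that the naming rule picks, 17, 8 and 8 stayed past the test without control 1, 2 and 3, and 15, 12 and 38 without knockout 1, 2 and 3; none changed sign in these omissions.

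Targets and feedback regulators of beta-catenin, the transcriptional effector of canonical Wnt signalling, were lower as a list, with a median log2 difference of -0.27. Of 19 tested members, 0 were higher, 3 were lower and 16 did not pass the test over all genes; 0 higher and 8 lower genes passed when adjusted over the list alone (camera adjusted p = 5.08e-08; adjusted p = 0.150 with an estimated correlation). Notum (ENSMUSG00000042988) had a log2 difference of -0.97 (SE 0.065; limma adjusted p = 0.00258). Apcdd1, a membrane inhibitor of Wnt signalling, fell from 41.0 ± 0.390 to 18.6 ± 1.28 TPM and the receptor gene Tnfrsf19 from 73.6 ± 3.87 to 42.1 ± 3.60 TPM (limma adjusted p = 0.00341 and 0.00964). Axin2, the negative feedback scaffold often used as a readout of the pathway, averaged 57.6 ± 5.21 TPM in controls and 44.7 ± 4.09 TPM in knockouts. Its log2 difference of -0.36 (SE 0.098) and that of Lef1, -0.32 (SE 0.11), did not pass the test over all genes (limma adjusted p = 0.200 and 0.323). The authors' deposited table gives an adjusted p of 0.00761 for Axin2 and 0.0778 for Lef1.

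**Figure D1:**
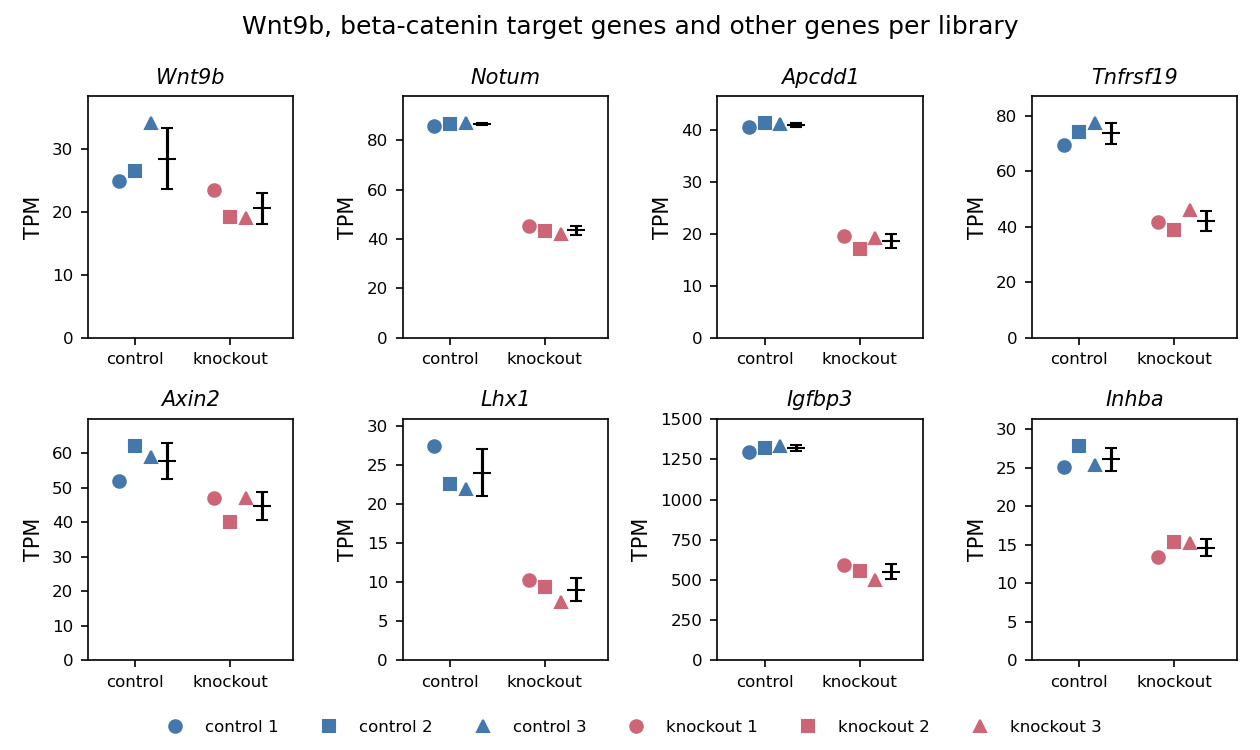
TPM (vertical axes, from 0) of Wnt9b, beta-catenin target genes and other genes of the text in each control and knockout library, 1 point per library, with the mean and SD of each group in black. Notum lies between 85.9 and 86.8 TPM in controls and between 41.8 and 45.5 TPM in knockouts; Wnt9b and Axin2 did not pass the test.

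Among other Wnt pathway genes, Rspo1, a secreted amplifier of Wnt signalling, and the R-spondin receptor gene Lgr4 rose, with log2 differences of 0.56 (SE 0.070) and 0.57 (SE 0.086; limma adjusted p = 0.0187 and 0.0354). Lgr4 averaged 54.1 ± 2.64 TPM in controls and 81.1 ± 8.01 TPM in knockouts. Wnt5a, a ligand that acts mainly outside the beta-catenin pathway, fell from 163 ± 1.17 to 115 ± 11.9 TPM (log2 difference -0.51; limma adjusted p = 0.0467). Of 32 tested Wnt ligands and receptors, 2 were higher, 1 was lower and 29 did not pass the test over all genes; 2 higher and 5 lower genes passed when adjusted over the list alone (camera adjusted p = 0.364). Wnt4, which drives epithelium formation in the kidney, averaged 173 ± 4.09 TPM in controls and 152 ± 5.75 TPM in knockouts, a log2 difference of -0.19 (SE 0.058). Wnt11 and Wnt7b differed by 0.016 and 0.0097; none of these 3 passed limma's test (adjusted p = 0.256, 0.968 and 0.992). None of 18 tested genes of planar cell polarity passed limma over all genes (4 at an unadjusted p under 0.05; 1 in the authors' deposited table). When adjusted over the list alone, 0 were higher and 2 lower (camera adjusted p = 0.0557). That p was 0.00464 without control 1 and 0.00617 without knockout 1, in the direction of lower, and the members Ptk7 and Prickle1 had log2 differences of -0.23 and -0.18.

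Of genes known to depend on Wnt9b in the mesenchyme of the permanent kidney, Lhx1 and the phospholipase gene Pla2g7 were lower. Pla2g7 fell from 24.2 ± 1.10 to 14.1 ± 1.11 TPM and Lhx1 from 24.0 ± 2.99 to 9.03 ± 1.46 TPM, with log2 differences of -0.74 and -1.32 (limma adjusted p = 0.0278 and 0.0123). Of 9 tested genes of that list, 0 were higher, 2 were lower and 7 did not pass the test over all genes; 0 higher and 3 lower genes passed when adjusted over the list alone (camera adjusted p = 0.00377; adjusted p = 0.232 with an estimated correlation). The median was -0.14, and the camera adjusted p was 0.0951 without knockout 3. In the list of Wolffian duct epithelium, which also holds Lhx1, the calcium-binding protein gene Calb1 fell from 13.9 ± 2.31 to 4.88 ± 1.09 TPM (limma adjusted p = 0.0281). The log2 differences of duct genes that did not pass the test were -0.27 for Pax2, -0.27 for Pax8, 0.027 for Gata3, 0.12 for Ret, 0.17 for Cdh1 and -0.092 for Emx2. Of 30 tested duct genes, 0 were higher, 2 were lower and 28 did not pass the test over all genes; 2 higher and 5 lower genes passed when adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.319 with an estimated correlation). The camera adjusted p was 0.227 without knockout 3. Among genes of the mesonephric tubules and nephron epithelium, the Iroquois transcription factor gene Irx1 fell from 2.95 ± 0.396 to 0.533 ± 0.250 TPM and the Notch ligand gene Jag1 from 57.0 ± 2.16 to 38.1 ± 3.22 TPM (limma adjusted p = 0.0454 and 0.0325). Of 18 tested tubule genes, 0 were higher, 2 were lower and 16 did not pass the test over all genes; 0 higher and 6 lower genes passed when adjusted over the list alone (camera adjusted p = 0.000293; adjusted p = 0.150 with an estimated correlation). Their median was -0.18. Of 13 tested Notch pathway genes, 0 were higher, 1 was lower and 12 did not pass the test over all genes; 1 higher and 3 lower genes passed when adjusted over the list alone (camera adjusted p = 0.0333; adjusted p = 0.176 with an estimated correlation). Jag1 was the lower one, and the camera adjusted p was 0.105 without control 1 and 0.340 without knockout 3.

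The lists of the ureteric bud tip and of the response to fibroblast growth factor share Spry1, Etv4 and Etv5. Spry1, a feedback inhibitor of that response, had a log2 difference of -0.43 (SE 0.073; limma adjusted p = 0.0569) and the ETS factor gene Etv5 one of -0.12 (SE 0.084). None of 11 tested tip genes passed limma over all genes (4 at an unadjusted p under 0.05; 3 in the authors' deposited table). Adjusted over the list alone, 0 were higher and 3 lower (camera adjusted p = 0.0113; adjusted p = 0.316 with an estimated correlation). The camera adjusted p was 0.279 without knockout 3. None of 16 tested genes of the fibroblast growth factor response passed limma over all genes (6 at an unadjusted p under 0.05; 3 in the authors' deposited table). 0 were higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0133; adjusted p = 0.176 with an estimated correlation). The camera adjusted p was 0.0793 without knockout 3; Dusp6 and Spred1, its members of highest level, had log2 differences of -0.26 and -0.13. None of 13 tested nephron progenitor genes passed limma over all genes (2 at an unadjusted p under 0.05; 0 in the authors' deposited table). The counts adjusted over the list alone were 0 higher and 0 lower (camera adjusted p = 0.731). The camera adjusted p was 0.0180 without knockout 3, in the direction of higher. Itga8 of that list averaged 189 ± 10.5 TPM in controls and 149.9 ± 39.1 TPM in knockouts and Rspo3 50.8 ± 0.921 TPM in controls and 56.8 ± 10.7 TPM in knockouts. Six2, under the filter, did not exceed 1.18 TPM in any library, and Fgf8 was not analysed here.

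Among androgen-related genes, Inhba, which encodes a subunit of activin A, fell from 26.1 ± 1.51 to 14.6 ± 1.05 TPM (limma adjusted p = 0.0187). Srd5a2, which converts testosterone to dihydrotestosterone, lay under the filter, at 0.640, 1.58 and 1.17 TPM in controls and 0.406, 0.371 and 0.298 TPM in knockouts. Fkbp5, induced by androgens and glucocorticoids, averaged 31.3 TPM in controls and 34.0 TPM in knockouts, a log2 difference of 0.12 (SE 0.086; limma adjusted p = 0.678). Of 20 tested androgen-related genes, 0 were higher, 1 was lower and 19 did not pass the test over all genes; 1 higher and 3 lower genes passed when adjusted over the list alone (camera adjusted p = 0.0560). The list median was -0.080, the camera adjusted p was 0.0487 without control 2, and the list passed fry, in the direction of lower (adjusted p = 0.0303).

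In the mesonephric mesenchyme list, the growth factor receptor gene Pdgfrb fell from 229 ± 15.7 to 151 ± 5.14 TPM and the transcription factor gene Tcf21 rose from 191 ± 12.6 to 295 ± 24.0 TPM (limma adjusted p = 0.0137 and 0.0197). Of 29 tested mesenchyme genes, 1 was higher, 1 was lower and 27 did not pass the test over all genes; 6 higher and 6 lower genes passed when adjusted over the list alone (camera adjusted p = 0.655). The signs differed (median -0.061, mean 0.049, camera direction lower). Tgfbi, a secreted matrix protein gene, fell from 953 ± 46.8 to 632 ± 41.3 TPM (limma adjusted p = 0.0156). Of 16 tested genes of the response to bone morphogenetic proteins and transforming growth factor beta, 0 were higher, 2 were lower and 14 did not pass the test over all genes; 0 higher and 2 lower genes passed when adjusted over the list alone (camera adjusted p = 0.957). The lower ones were Tgfbi and Inhba, and the signs differed (median 0.095, mean -0.038, camera direction lower). The retinoic acid binding protein gene Crabp1 fell from 240.5 ± 12.7 to 155 ± 7.04 TPM, and Crabp2 rose from 110.3 ± 2.40 to 155 ± 6.66 TPM (limma adjusted p = 0.00960 and 0.0181). Of 12 tested retinoic acid genes, 1 was higher, 1 was lower and 10 did not pass the test over all genes; 3 higher and 4 lower genes passed when adjusted over the list alone (camera adjusted p = 0.897). The signs differed (median -0.063, mean 0.033, camera direction lower). The transcription factor gene Hand2 fell from 69.7 ± 1.51 to 45.5 ± 5.36 TPM, and the neighbouring long noncoding RNA gene Hand2os1 from 13.9 ± 1.16 to 4.61 ± 1.67 TPM (limma adjusted p = 0.0382 and 0.0314). The strand setting of the counting is not given, so reads of these 2 neighbours are not known to be fully told apart. None of 8 tested hedgehog response genes passed limma over all genes (1 at an unadjusted p under 0.05; 1 in the authors' deposited table). When adjusted over the list alone, 0 were higher and 0 lower (camera adjusted p = 0.738). The signs differed (median -0.0064, mean 0.25, camera direction higher), and Gli1 averaged 97.1 ± 1.59 TPM in controls and 96.3 ± 18.0 TPM in knockouts and Gas1 377 ± 23.4 TPM in controls and 364 ± 14.6 TPM in knockouts.

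The decreases that the naming rule picks by size began with Prss56, a serine protease gene, which fell from 6.03 ± 0.988 to 0.775 ± 0.544 TPM, Ctxn3 (4.20 ± 2.06 to 0.235 ± 0.149 TPM) and Spp2 (4.97 ± 0.459 to 0.634 ± 0.510 TPM). Their log2 differences were -2.02, -2.01 and -1.91. Npy, which encodes neuropeptide Y, averaged 95.0 ± 22.3 TPM (SD, n = 3) in controls and 25.8 ± 2.00 TPM in knockouts (log2 difference -1.82, SE 0.16; limma adjusted p = 0.00519). Spp1, the osteopontin gene, fell from 45.2 ± 5.59 to 14.9 ± 1.45 TPM (limma adjusted p = 0.00341). The ATP-gated channel gene P2rx2 fell from 14.4 ± 1.12 to 4.56 ± 0.976 TPM, the synaptic adhesion gene Lrrtm1 from 29.4 ± 3.97 to 10.5 ± 0.713 TPM and the monooxygenase gene Moxd1 from 84.5 ± 17.1 to 31.9 ± 2.37 TPM. The kainate receptor gene Grik1 had a log2 difference of -1.39 (SE 0.14). The limma adjusted p of these 4 genes lay between 0.00525 and 0.0106. Among the increases, Kctd14 averaged 5.69 ± 2.32 TPM (SD, n = 3) in controls and 30.8 ± 5.05 TPM in knockouts (log2 difference 2.29, SE 0.23; limma adjusted p = 0.00858). The synaptic organiser gene Cbln1 rose from 0.668 ± 0.600 to 6.76 ± 1.26 TPM, Fxyd4, a regulator of the sodium pump, from 2.97 ± 0.630 to 8.06 ± 0.870 TPM, the aldo-keto reductase gene Akr1b8 from 30.8 ± 1.52 to 56.7 ± 2.28 TPM and Reep2 from 10.8 ± 1.41 to 20.2 ± 1.45 TPM.

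Genes of Sertoli and gonadal somatic cells were higher as a list, with a median of 1.07. Of 14 tested gonadal somatic genes, 4 were higher, 0 were lower and 10 did not pass the test over all genes; 7 higher and 1 lower gene passed when adjusted over the list alone (camera adjusted p = 7.83e-07; adjusted p = 0.176 with an estimated correlation). Nr5a1 had a log2 difference of 1.62 (SE 0.22; limma adjusted p = 0.0281) and Gata4 one of 1.82 (SE 0.27; limma adjusted p = 0.0354). Nr0b1, which encodes the nuclear receptor DAX1, rose from 4.10 ± 0.882 to 11.5 ± 2.23 TPM, and the inhibin and activin subunit gene Inhbb from 2.46 ± 0.558 to 8.18 ± 1.42 TPM. Amh, the anti-Mullerian hormone gene of Sertoli cells, was at 10.5, 5.87 and 4.33 TPM in controls and 67.8, 44.6 and 9.58 TPM in knockouts and did not pass the test (limma adjusted p = 0.244). Lhx9, a homeobox gene of the gonad and coelomic epithelium, rose from 4.78 ± 1.66 to 15.5 ± 3.52 TPM (limma adjusted p = 0.0463), while Wnt7a of the Mullerian duct had a log2 difference of -0.42 (SE 0.12; limma adjusted p = 0.226). Of 16 tested genes of the coelomic epithelium and Mullerian duct, 1 was higher, 0 were lower and 15 did not pass the test over all genes; 3 higher and 1 lower gene passed when adjusted over the list alone (camera adjusted p = 0.700). The signs differed (median -0.064, mean 0.051, camera direction higher).

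Germ cell genes, which mark testis tissue, varied between libraries of both groups: Dppa3 was at 16.6, 1.09 and 1.68 TPM in controls and 19.0, 8.55 and 4.55 TPM in knockouts. None of 13 tested germ cell genes passed limma over all genes (0 at an unadjusted p under 0.05; 0 in the authors' deposited table). Adjusted over the list alone, 0 were higher and 0 lower (camera adjusted p = 0.0452; adjusted p = 0.593 with an estimated correlation). The list median was 0.51, with 10 members above 0 and 3 below, and camera's direction was higher, as for the gonadal somatic genes. The camera adjusted p was 0.319 without control 2, 0.238 without control 3, 0.246 without knockout 1 and 0.268 without knockout 2. It was 9.79e-05 without control 1 and 0.00223 without knockout 3. Dppa5a and Kit, the list's members of highest level, had log2 differences of 0.51 and -0.10. None of 7 tested steroidogenic genes passed limma over all genes (3 at an unadjusted p under 0.05; 1 in the authors' deposited table). 3 were higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00212; adjusted p = 0.150 with an estimated correlation). Hsd3b6 averaged 22.9 ± 4.43 TPM in controls and 22.0 ± 1.60 TPM in knockouts and Fdx1 21.0 ± 1.24 TPM in controls and 20.5 ± 2.41 TPM in knockouts.

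**Figure D2:**
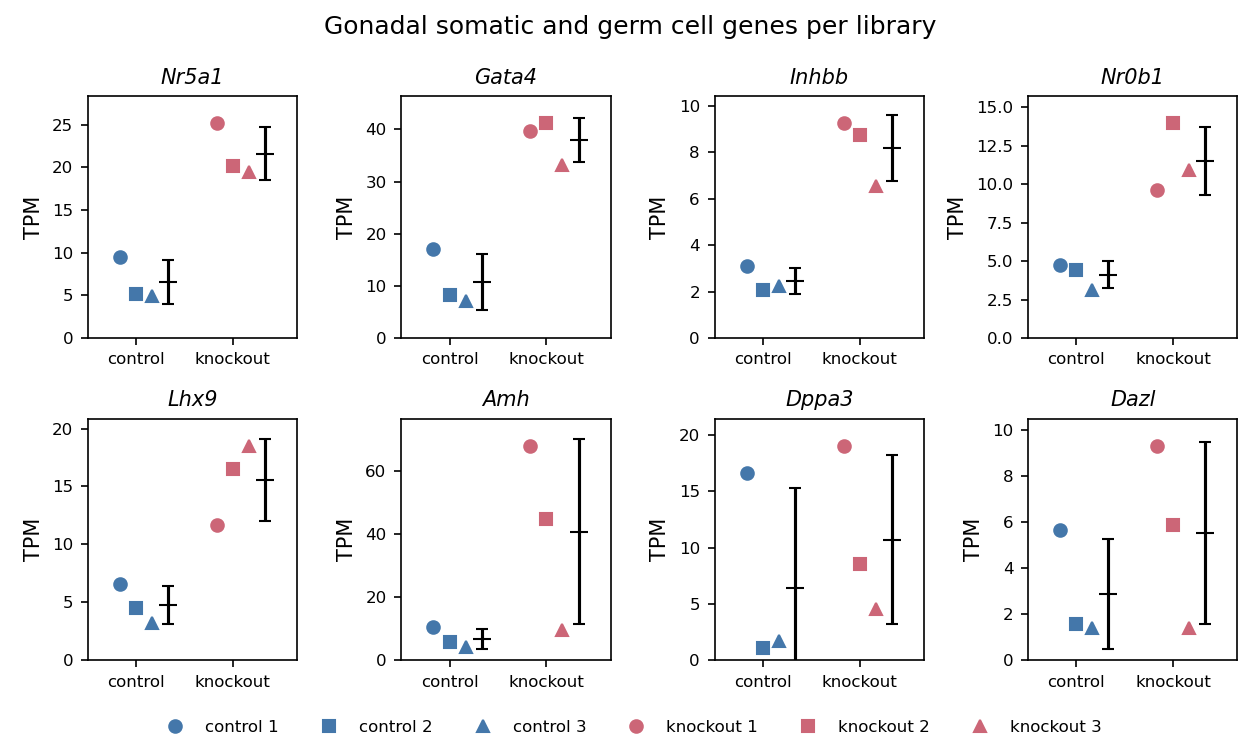
TPM (vertical axes, from 0) of gonadal somatic genes (Nr5a1, Gata4, Inhbb, Nr0b1, Lhx9, Amh) and germ cell genes (Dppa3, Dazl) in each control and knockout library, 1 point per library, with the mean and SD of each group in black. Gata4 lies between 7.02 and 17.0 TPM in controls and between 33.2 and 41.2 TPM in knockouts, whereas the germ cell genes overlap between the groups.

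Col2a1, the main collagen gene of cartilage, averaged 5.43 ± 0.855 TPM (SD, n = 3) in controls and 19.1 ± 3.40 TPM in knockouts, and Col9a1 rose from 1.70 ± 0.431 to 5.43 ± 0.221 TPM (limma adjusted p = 0.00858 and 0.0337). Of 6 tested genes of chondrocytes and skeletal mesenchyme, 2 were higher, 0 were lower and 4 did not pass the test over all genes; 3 higher and 1 lower gene passed when adjusted over the list alone (camera adjusted p = 0.000974; adjusted p = 0.150 with an estimated correlation). None of 5 tested skeletal muscle genes passed limma over all genes (4 at an unadjusted p under 0.05; 1 in the authors' deposited table). The counts adjusted over the list alone were 4 higher and 0 lower (camera adjusted p = 9.03e-05; adjusted p = 0.176 with an estimated correlation). The cardiac actin gene Actc1 of that list was at 4.57, 15.9 and 34.2 TPM in knockouts and did not exceed 5.55 TPM in controls, and Tnnt1 averaged 18.7 ± 1.16 TPM in controls and 31.0 ± 3.94 TPM in knockouts. None of 8 tested smooth muscle genes passed limma over all genes (4 at an unadjusted p under 0.05; 3 in the authors' deposited table). When adjusted over the list alone, 1 was higher and 0 lower (camera adjusted p = 0.00484; adjusted p = 0.160 with an estimated correlation). Acta2 averaged 41.3 ± 7.72 TPM in controls and 60.7 ± 17.3 TPM in knockouts and Mylk 29.9 ± 0.544 TPM in controls and 25.5 ± 1.77 TPM in knockouts. Of 12 tested genes of neural crest, glia and neurons, 0 were higher, 1 was lower and 11 did not pass the test over all genes; 1 higher and 1 lower gene passed when adjusted over the list alone (camera adjusted p = 0.0557). Hand2 was the lower one, whereas the median was 0.68, and the camera adjusted p was 0.0463 without control 1 and 0.000184 without knockout 3. None of 7 tested genes of liver and gut epithelium passed limma over all genes (2 at an unadjusted p under 0.05; 2 in the authors' deposited table). Adjusted over the list alone, 1 was higher and 0 lower (camera adjusted p = 0.174). That p was 0.0425 without knockout 2. Albumin, Alb, was at 27.9 TPM in knockout 3 and at no more than 2.34 TPM in the other 5 libraries. Shh was at 21.5 TPM in knockout 1 and no more than 9.92 TPM elsewhere, and transferrin, Trf, averaged 20.2 ± 2.43 TPM in controls and 19.7 ± 5.42 TPM in knockouts.

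Proliferation genes lay mostly above 0, 28 of 30, with a median of 0.20. None of 30 tested proliferation genes passed limma over all genes (14 at an unadjusted p under 0.05; 8 in the authors' deposited table). 12 were higher and 0 lower when adjusted over the list alone (camera adjusted p = 3.49e-12; adjusted p = 0.150 with an estimated correlation). Top2a, the topoisomerase gene of dividing cells, averaged 194 ± 5.79 TPM in controls and 222 ± 10.5 TPM in knockouts and the replication helicase gene Mcm3 209 ± 3.86 TPM in controls and 219 ± 10.4 TPM in knockouts. None of 13 tested genes of the mitochondrial genome passed limma over all genes (3 at an unadjusted p under 0.05; 0 in the authors' deposited table). The counts adjusted over the list alone were 0 higher and 0 lower (camera adjusted p = 7.63e-05; adjusted p = 0.168 with an estimated correlation). All 13 lay above 0, with a median of 0.18, and mt-Co1 and mt-Cytb had log2 differences of 0.13 and 0.18. Transcripts of the mitochondrial genome took 6.39% ± 0.212 of TPM in controls and 6.94% ± 0.330 in knockouts (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The ribosomal RNA gene Rn18s-rs5, whose RNA poly(A) selection is meant to remove, took 2.85% ± 0.355 in controls and 1.83% ± 0.145 in knockouts (exact permutation p = 0.1). It ran from 2.53% to 3.23% in controls and from 1.70% to 1.99% in knockouts, and neither share overlapped between the groups. The labels give no batch, so a difference in RNA handling or library preparation cannot be told apart from the genotype here. None of 18 tested cholesterol synthesis genes passed limma over all genes (2 at an unadjusted p under 0.05; 0 in the authors' deposited table). When adjusted over the list alone, 0 were higher and 0 lower (camera adjusted p = 0.000974; adjusted p = 0.266 with an estimated correlation). The median was 0.16; Hmgcs1 averaged 71.4 ± 7.33 TPM in controls and 82.0 ± 6.23 TPM in knockouts, and Srebf2 had a log2 difference of 0.098. None of 20 tested genes of hypoxia and glycolysis passed limma over all genes (6 at an unadjusted p under 0.05; 3 in the authors' deposited table). Adjusted over the list alone, 0 were higher and 3 lower (camera adjusted p = 0.000974; adjusted p = 0.150 with an estimated correlation). The median was -0.15. Ldha, the lactate dehydrogenase gene, averaged 585 ± 25.4 TPM in controls and 492 ± 16.6 TPM in knockouts, and the enolase gene Eno1 had a log2 difference of -0.014.

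All 12 endothelial genes lay below 0, with a median of -0.24. None of 12 tested endothelial genes passed limma over all genes (4 at an unadjusted p under 0.05; 2 in the authors' deposited table). 0 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 9.03e-05; adjusted p = 0.175 with an estimated correlation). Cdh5, the vascular cadherin gene, averaged 107 ± 2.82 TPM in controls and 88.0 ± 4.08 TPM in knockouts, and Plvap had a log2 difference of -0.048. None of 20 tested genes of basement membrane and extracellular matrix passed limma over all genes (8 at an unadjusted p under 0.05; 5 in the authors' deposited table). The counts adjusted over the list alone were 1 higher and 2 lower (camera adjusted p = 0.000293; adjusted p = 0.408 with an estimated correlation). Their median was -0.16, and the collagen gene Col4a1 and the integrin gene Itgb1 had log2 differences of -0.071 and -0.14. None of 12 tested erythroid genes passed limma over all genes (2 at an unadjusted p under 0.05; 0 in the authors' deposited table). When adjusted over the list alone, 0 were higher and 0 lower (camera adjusted p = 0.00971; adjusted p = 0.316 with an estimated correlation). The median was 0.22, the camera adjusted p was 0.0621 without control 3 and 0.227 without knockout 3, and the globin genes Hba-a1 and Hbb-y had log2 differences of 0.36 and 0.061. Haemoglobin transcripts took 1.55% ± 0.218 of TPM in controls and 1.72% ± 0.113 in knockouts (SD, n = 3; exact permutation p = 0.400). None of 11 tested macrophage genes passed limma over all genes (1 at an unadjusted p under 0.05; 0 in the authors' deposited table). Adjusted over the list alone, 0 were higher and 0 lower (camera adjusted p = 0.0622). That p was 0.000455 without control 3; C1qa and C1qb of the complement system had log2 differences of -0.18 and -0.26. None of 18 tested targets of p53 passed limma over all genes (5 at an unadjusted p under 0.05; 3 in the authors' deposited table). 0 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.283). The list passed fry (adjusted p = 0.0178), and Plk2 and Phlda3 had log2 differences of -0.33 and 0.0070. None of 16 tested immediate early genes passed limma over all genes (4 at an unadjusted p under 0.05; 0 in the authors' deposited table). The counts adjusted over the list alone were 0 higher and 0 lower (camera adjusted p = 0.805). The signs differed (median -0.15, mean -0.029, camera direction higher), the camera adjusted p was 0.00655 without knockout 2 in the direction of lower, and Jun and Ier2 had log2 differences of -0.16 and -0.17.

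Of 34 lists, 20 passed camera with its preset correlation, 10 higher and 10 lower. Beta-catenin target genes were the list with the lowest median among these and gonadal somatic genes that with the highest. With a correlation estimated for each list, camera called 0 of the 34, with 9 at an unadjusted p under 0.05. Fry, which asks whether the genes of a list move 1 way, called 16 of the 34: 14 of those past camera with the preset correlation and 2 others, the androgen-related genes and the targets of p53.

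**Figure D3:**
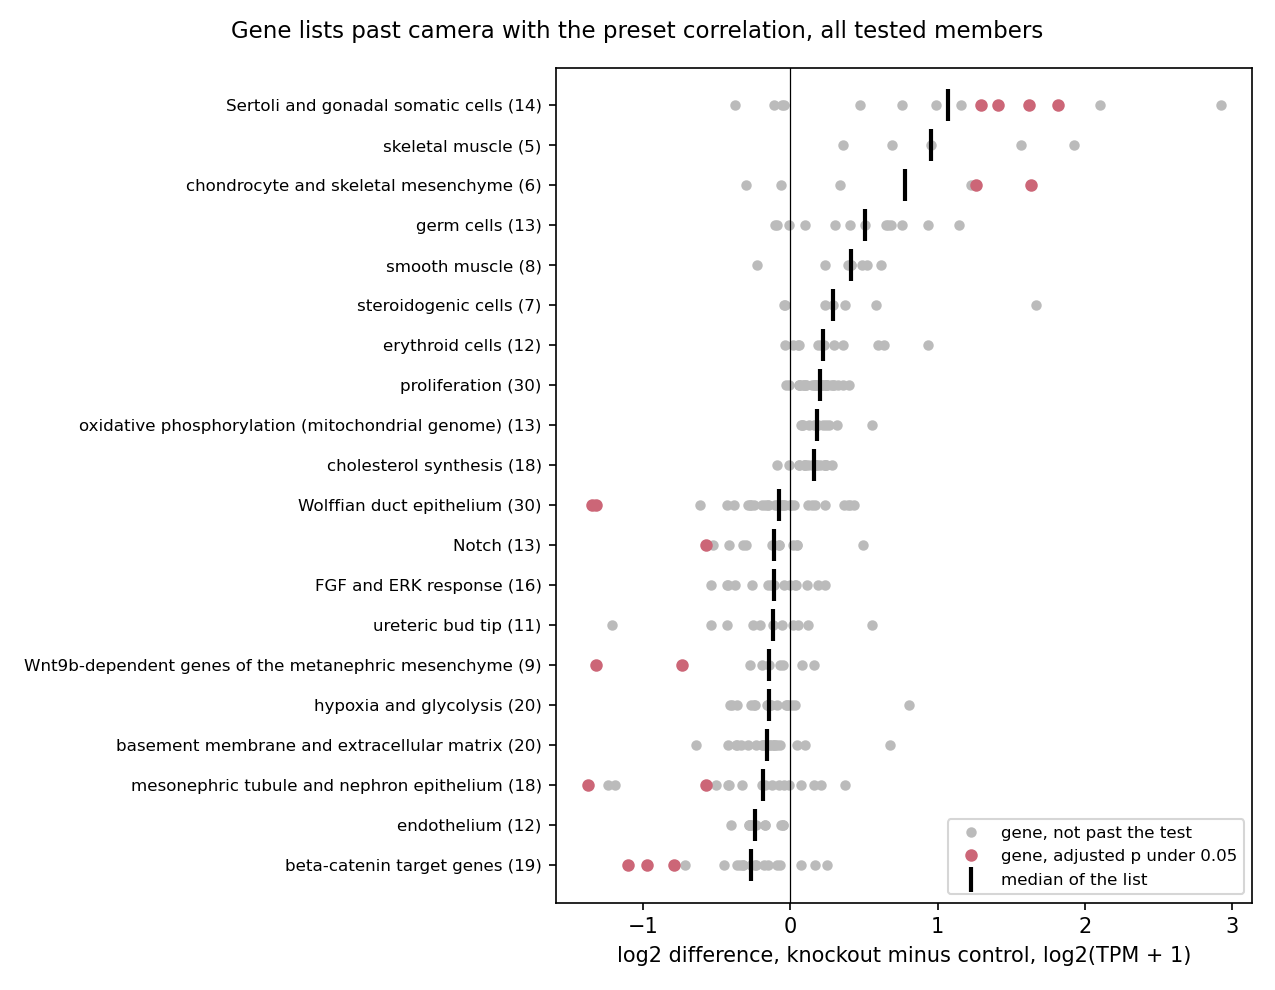
Log2 difference between knockout and control (horizontal axis, on the log2(TPM + 1) scale) of each tested member of the gene lists past camera with the preset correlation, 1 row per list with its number of tested genes. Red points passed limma over all genes, grey points did not and black bars are list medians, which run from -0.27 for beta-catenin target genes to 1.07 for gonadal somatic genes.

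Between libraries of a group, the lowest Pearson r of log2(TPM + 1) was 0.975 over the tested genes. The first principal component held 29.7% of the variance and set knockout 1 (29.5) and knockout 2 (24.5) apart from the controls, which lay between -16.4 and -15.2. Knockout 3 lay at -7.28 on it and stood apart from the other 5 libraries on the second component (-36.7; 23.6% of the variance).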

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

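The filter at 5 TPM, the pseudocount of 0.1 with the filter kept and the library weights were chosen after seeing the data. The count of 78 genes stayed between 72 and 106 with other scalings, filters and pseudocounts and with erythroid genes removed. It rose to 295 with limma-voom, 285 with library weights and 670 in the authors' deposited table, and fell to 20 at an adjusted p under 0.01 and 22 for a change over 1.2-fold; the cause was not tested beyond the stricter thresholds themselves. Without 1 library it ranged from 13 (control 2) to 243 (knockout 3); leaving out control 1, control 3, knockout 1 or knockout 2 also moved it by over 1.5 times, to 28, 14, 33 and 23 (the cause was not tested). Of the 78 genes, 76 were also called without knockout 3 and 77 with limma-voom, and the sign of none changed under these alternatives. A replicate block gave 17 genes and 21 lists. Same-numbered mice deviated from their group means with correlations of -0.064, 0.050 and -0.051, so no pairing by number was seen. Shared litters or batches are not excluded by this, since the labels give none. The Wnt9b difference stayed between -0.54 and -0.31, past the threshold only in the authors' deposited table (-0.45, adjusted p 0.0263; adjusted p from 0.0263 to 1.00 over its alternatives). The count of lists fell to 0 with an estimated correlation and otherwise lay between 16 and 22. The immediate early list turned from higher to lower without knockout 2 (camera adjusted p = 0.00655, against up to 0.894 without another library and 0.954 over its alternatives); the cause was not tested. The lowest correlation within a group was 0.975 and moved to 0.960 with a pseudocount of 0.1, which weights low genes more. Over named genes, 1532 values under alternatives kept the call or its absence, 217 lost the call and 25 gained it. Over lists, 347, 45 and 15 did. A change of sign between values that both missed the threshold was counted as kept, as for Wnt7b, which ran from -0.20 to 0.24. The planned filter of 1 unit in 3 libraries is the one used, and DESeq2 was not run here, since the main unit is TPM.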

Other observations

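Genes named in this part, the 5 caudal genes and the tests of this part, except the counts over other splits of the libraries, were chosen after the values were seen. Genes of the caudal end of the trunk were high in knockout 1 and knockout 2 and low in knockout 3. The posterior Hox genes Hoxd13 and Hoxa13 were at 114 and 54.4 TPM in knockout 1, 53.1 and 31.2 TPM in knockout 2, and 6.83 and 2.54 TPM in knockout 3. Controls lay between these, at 17.1, 18.4 and 16.1 TPM for Hoxd13 and 9.29, 10.3 and 13.7 TPM for Hoxa13. Isl1 was at 66.9, 32.9 and 2.44 TPM in knockouts and between 10.6 and 13.9 TPM in controls, and Evx1 at 22.3, 8.74 and 0.415 TPM in knockouts and at no more than 4.12 TPM in controls. The forkhead gene Foxf1 of visceral mesenchyme was at 34.6, 15.7 and 2.27 TPM in knockouts and did not exceed 1.86 TPM in controls. None of these 5 genes passed limma between the groups, while the authors' deposited table gives an adjusted p of 0.0164 for Foxf1.

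Liver genes were high in knockout 3, with Afp at 38.1 TPM and Apoa2 at 13.1 TPM, where Afp did not exceed 3.63 TPM and Apoa2 was listed at 0 in the other 5 libraries. The fast muscle gene Mylpf was at 4.50, 7.40 and 17.1 TPM in knockouts and did not exceed 4.93 TPM in controls. Neutrophil genes were high in control 1, with S100a8 at 61.3 TPM and S100a9 at 99.2 TPM, and next highest in knockout 3 at 24.6 and 44.4 TPM. The testis genes Cst9 and Cyp17a1 were at 19.9, 13.2 and 3.82 TPM and 2.75, 1.68 and 0.129 TPM in knockouts, and did not exceed 1.41 and 0.0740 TPM in controls.

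Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes past limma's test as the real one: the real split itself, with 78, where the highest of the others was 0; those 9 gave 365 to 1532 genes at an unadjusted p under 0.05, against 1981. For gene lists, 1 of 10 splits, the real one, reached 20 lists by camera with the preset correlation, and the others gave 4 to 11. 10 splits are too few for a share under 0.05.

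The higher level of Nr5a1, Gata4, Nr0b1 and Inhbb in knockouts may come from testis tissue carried over at dissection or from the genotype. With the germ cell list as a covariate, the median log2 difference of these 4 genes went from 1.52 (median SE 0.21) to 1.31 (median SE 0.18). The 4 genes were picked for a difference between the groups, whereas 0 germ cell genes differed at an unadjusted limma p under 0.05. Such a covariate could hardly remove the difference, so the fit does not weigh against testis tissue. All 4 kept an unadjusted p under 0.05 and 1 passed the adjusted threshold; the other 3 calls ended in a fit with 1 residual degree of freedom less, which called 34 genes in all. Carried-over gonadal tissue, with or without germ cells, stays open, as does the genotype, which was not tested apart from it.

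The 55 lower genes, with a median log2 difference of -0.82 (median SE 0.097), could reflect tissue makeup or the genotype. The mean of the 5 caudal genes Hoxa13, Hoxd13, Hoxd12, Evx1 and Isl1 was used as a covariate. The median was then -0.79 (median SE 0.090), 55 of 55 kept their sign and 43 passed the adjusted threshold. In these 5 genes the knockouts lay on both sides of the controls, whereas the lower genes were picked for a difference between the groups. A gene that follows caudal content would rarely be among the 55, so this fit does not weigh on the caudal extent of the pieces. A smaller share of mesonephric mesenchyme, or of duct and tubule epithelium, would lower all markers of that tissue. Their medians were -0.061 over 29 genes (SD 0.62) and -0.11 over 48 genes (SD 0.45), with 12 and 14 members above 0. Both medians lay above that of the lower genes by more than the SD of the members. The lower genes were picked for their fall, so a gap was built in and does not weigh against a slightly smaller share. The markers were fixed before the data were examined, so their medians were free to fall. For the genes they cover, they argue against a fall of either whole tissue as large as -0.82. The tubule genes alone had a median of -0.18, with 14 below 0 and 4 above. The caudal extent and a lesser fall in the share of these tissues stay open. So do a loss of a small cell population that these lists do not mark and the genotype.

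Tdg-ps2, annotated as a pseudogene of the DNA repair gene Tdg, averaged 0.737 ± 0.0979 TPM (SD, n = 3) in controls and 28.5 ± 16.5 TPM in knockouts (limma adjusted p = 0.00960). In knockouts 1, 2 and 3 it was at 29.5, 11.6 and 44.5 TPM while Tdg was at 41.1, 48.2 and 15.1 TPM. Their sum averaged 59.1 ± 9.94 TPM in controls and 63.3 ± 6.29 TPM in knockouts, a log2 difference of 0.11 (SE 0.16), where Tdg-ps2 transcripts added to the control level of Tdg would give 0.56. The hypothesis that reads of Tdg are counted for its copy fits this sum if the 2 genes have like lengths. TPM divides reads by gene length, so reads moved between genes of unlike length would change the sum. The lengths are not given. A sequence difference of Tdg between the mice, which could make reads of Tdg count for its copy, was not tested.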
